A study of Mus musculus with 12 samples.

How the data were processed

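RNA from 12 mammary tumours of MMTV-PyMT mice, in which the polyoma middle T antigen is driven from the mouse mammary tumour virus promoter, was measured with the nCounter Mouse PanCancer IO360 panel. This assay counts fluorescent barcodes bound to a chosen set of transcripts. Per the labels' protocols, RNA was extracted from small pieces of snap-frozen tumour with a column kit, copied into cDNA and enriched for the panel's targets by multiplex amplification before counting. The 5 groups came from the treatment labels: PTX (2 samples), PLX+PTX (2), PLX+PTX+aPD-1 with the suffix R (3), the same with the suffix NR (3), and PLX+PTX+aPD-L1 (2). Per the series title, the study joined inhibition of the receptor CSF1R with chemotherapy. The labels do not expand R and NR, which are kept as written, and these groups are called R and NR. Replicates were numbered in order of deposition, so the numbers name libraries and pair none of them.

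The deposited raw table holds whole-number counts for 784 probes, of which 750 were endogenous, 20 housekeeping, 6 positive-control and 8 negative-control probes, per the file headers. The deposited processed table holds log2 values of the endogenous and housekeeping probes; the submitters' processing notes name DESeq2 and limma without saying what each was used for. Set against the raw counts, these log2 values carried a further adjustment that differed from gene to gene, and its method is not given in the sources used here. The raw counts were therefore analysed, and the deposited log2 values served as an alternative. Of the 770 probe identifiers of endogenous and housekeeping genes, 748 were found in a RefSeq gene table of assembly GRCm38.p6, 742 with the same symbol and 6 under a newer one. Symbols are printed as in the deposited table, and no coordinates were used.

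Total endogenous counts ran from 98741 to 531086 per library. Each library was scaled by the geometric mean of its 20 housekeeping probes, with scale factors from 0.346 to 1.80. The detection limit of a library was the mean of its negative-control probes plus 2 SD, and it lay between 19.1 and 35.6 counts. Scaling lifts this background together with the signal, so a library with a low housekeeping signal has a high scaled background. Means ± SD are of housekeeping-scaled (normalised) counts. Counting error adds to the spread for the many probes near the detection limit, where a fold change is also damped by the background.

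Endogenous probes with a raw count of 20 or more in at least 2 libraries were tested (615 of 750, with 135 left out). All 12 libraries entered one fit of 5 group means with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3; 7 residual degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. In all, 6 comparisons were made: PLX+PTX against PTX, R against NR, R and NR each against PLX+PTX, PLX+PTX+aPD-L1 against PLX+PTX, and PLX+PTX+aPD-L1 against the mean of R and NR. No label says that the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may in part be technical. No pair of libraries matched within sampling noise: the lowest chi-square per degree of freedom was 15.9 between libraries of the same group.

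Before the data were examined, 23 gene lists (cell types, pathways and processes), the rule for named genes and 10 fixed genes were set. Lists with 5 or more tested members, 19 in all, were tested with fry (limma 3.58.1). Its directional p asks whether the genes of a list move, on balance, one way, its mixed p whether they change in either direction, and neither compares a list with other genes. The camera test, which compares a list with the other genes, was run with a preset correlation of 0.01 between genes and again with an estimated correlation. With the estimated correlation no list passed in any of the 6 comparisons. The named genes of a comparison were the 6 largest rises and 6 largest falls past the threshold (with fewer than 6 in all, the genes of smallest p up to 6), up to 4 members of smallest p of each list past fry, and the 10 fixed genes. A gene that this rule takes is not reported here. Genes named outside that rule are said to have been chosen after their values were seen.

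The procedures were tested on simulated counts for the same 615 genes, 200 of them changed, in 5 simulations per comparison. For PLX+PTX against PTX, 23.4% of 2-fold and 86.8% of 4-fold changes were recovered, with 3.00% false calls. The shares recovered were 45.4% and 96.8% for R against NR, 36.0% and 91.6% for R against PLX+PTX, and 37.0% and 94.8% for NR against PLX+PTX. They were 25.2% and 81.8% for PLX+PTX+aPD-L1 against PLX+PTX, and 45.0% and 93.4% for PLX+PTX+aPD-L1 against the mean of R and NR. The simulated folds acted on the whole count, without a separate background, and the scale factors were known. These rates are therefore likely too favourable for probes near the detection limit, where background damps a fold and scaling shifts it.

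Alternatives set before the data were examined were TMM and median-of-ratios scaling, housekeeping scaling without the 3 least steady probes, DESeq2 1.42.0, limma-voom, a fit of the compared groups alone, no filter, a filter at 50 counts, counts raised to the detection limit, the deposited log2 values with limma, and leaving out each library in turn. A further 3 were added after the data were seen: the negative-control mean subtracted before scaling, followed by limma on log2(value + 20); leaving out the 3 libraries of low signal; and testing only probes above the detection limit in 10 or more libraries. The pseudocount of 20 understates the change of low genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.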

Results

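Immune and tumour transcripts were counted in 12 MMTV-PyMT mammary tumours from 5 treatment groups. PTX stood for the chemotherapy alone (n = 2) and PLX+PTX for chemotherapy with the CSF1R inhibitor (n = 2). An antibody against PD-1, a receptor on T cells, was added in the groups labelled R (n = 3) and NR (n = 3). The PLX+PTX+aPD-L1 group (n = 2) had an antibody against PD-L1, the ligand of PD-1. Total endogenous counts were 298726 to 531086 in 9 libraries. They were 98741 to 141021 in the other 3, which were R replicate 2 and both PLX+PTX+aPD-L1 libraries. The housekeeping geometric mean was 86.6 to 189 counts in these 3 and 260.4 to 450.2 in the other 9, while the positive controls gave 968 to 1401 counts in all 12.

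Genes of proliferation and of macrophages and monocytes were mostly above the detection limit in these tumours, while those of lymphocytes, dendritic cells and neutrophils were mostly near background. Of 750 endogenous probes, 329 lay above the detection limit in all 12 libraries and 148 in none. Spp1, which encodes the secreted matrix protein osteopontin, took 7.94% to 21.3% of the endogenous counts in 11 libraries and 2.29% in PLX+PTX+aPD-L1 replicate 1; it is named here after its values were seen. Of 19 macrophage and monocyte genes on the panel, 15 lay above the limit in 6 or more libraries, and so did 17 of 18 proliferation genes. The same held for 1 of 17 T cell genes, 1 of 14 CD8 and cytotoxic effector genes, 1 of 10 dendritic cell genes and 3 of 12 neutrophil and granulocytic genes. Among the fixed genes, Cd8a (5 to 27 raw counts), the PD-1 gene Pdcd1 (4 to 14), Ifng (3 to 7), Cxcl9 (5 to 18) and Foxp3 (4 to 12) were above the limit in no library. These 5 genes were not tested. The lists of regulatory T cell, NK cell, B cell and plasma cell, and epithelial genes had 3, 3, 3 and 4 tested members and were not tested as lists.

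**Figure D1:**
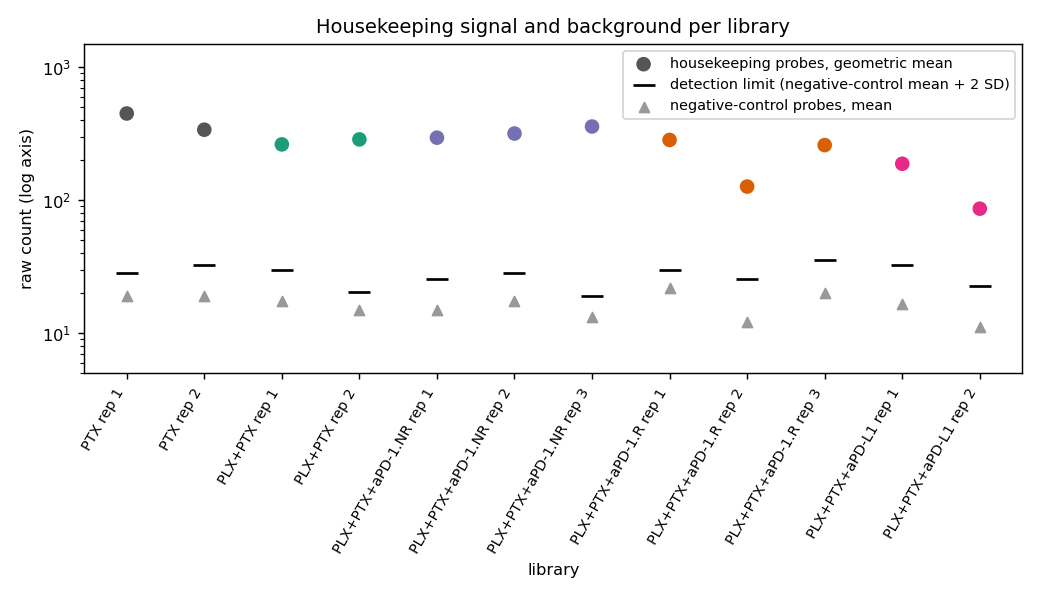
Raw counts on a log axis for each of the 12 libraries: circles are the geometric mean of the 20 housekeeping probes, triangles the mean of the negative-control probes, and dashes the detection limit. The housekeeping signal of R replicate 2 and both PLX+PTX+aPD-L1 libraries lies between 86.6 and 189, under that of the other 9 (260.4 to 450.2), while the negative-control mean stays between 11.3 and 21.9 in all 12.

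The comparison of PLX+PTX with PTX asks what adding CSF1R inhibition did to tumours under chemotherapy. Csf1r, the receptor on which macrophages depend, averaged 164 ± 43.2 normalised counts in PLX+PTX and 226 ± 132 in PTX (SD, n = 2 each; log2 fold change −0.46, SE 0.46). The monocyte-attracting chemokine gene Ccl12 averaged 104 ± 16.1 against 51.7 ± 5.48, and Ifit3, an interferon-induced gene, 212 ± 161 against 61.2 ± 0.877. S100a9, a calcium-binding protein of neutrophils, averaged 13.1 ± 2.41 in PLX+PTX and 57.8 ± 59.8 in PTX (log2 fold change −2.14, SE 0.74). Cd40, a costimulatory receptor of antigen-presenting cells, had a log2 fold change of 1.004 (SE 0.34), the cytotoxic granule protease gene Gzma one of 1.44 (SE 0.53), and the transcription factor gene Sox2 one of 0.96 (SE 0.36). Ccl12, Ifit3, S100a9, Cd40, Gzma and Sox2 had the smallest p-values and did not pass the threshold. The proliferation gene Mki67 averaged 1966 ± 205 against 1893 ± 11.8, and Gzmb, another granule protease, 27.0 ± 7.34 against 20.0 ± 3.23. The log2 fold changes of Cd274, which encodes PD-L1, and of the integrin gene Itgae were −0.04 (SE 0.54) and 0.30 (SE 0.63). By edgeR's quasi-likelihood test 0 of 615 genes changed (smallest adjusted p = 0.996), with 12 at an unadjusted p under 0.05; DESeq2 and limma-voom also gave 0.

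Interferon-induced genes had the highest list median of this comparison. The type I interferon response list had a median log2 fold change of 0.92, with 14 of 16 members above 0. Its members Irf7, the master regulator of that response, averaged 845 ± 610 in PLX+PTX and 248 ± 58.1 in PTX, and Isg15 789 ± 492 against 310 ± 70.2 (SD, n = 2 each). All 7 members of the CD8 and cytotoxic effector list lay above 0 (median 0.60), among them the granule protein gene Nkg7 (0.90, SE 0.45) and the chemokine gene Ccl5 (0.74, SE 0.52). Of 10 genes of MHC class I presentation, 9 lay above 0 (median 0.32). The macrophage and monocyte list had a median of −0.12, with 11 of 17 members below 0, including the scavenger receptor Cd163 (−0.73, SE 0.41) and the mannose receptor Mrc1 (−0.77, SE 0.50). The neutrophil list had a median of −0.27 and the proliferation list one of 0.12; the T cell list had a median of −0.03, a mean of 0.02 and a directional test pointing up. The list members beyond Csf1r, Gzma, Gzmb, Ifit3 and Mki67 were chosen after their values were seen. None of the 19 lists passed fry (adjusted p from 0.967 to 0.975), and in each of the lists described here 0 genes passed when adjusted over the list alone. With its preset correlation camera called the type I interferon list (adjusted p = 1.9e-05), the CD8 list (0.000747) and the MHC class I list (0.0363), and each had an adjusted p = 0.813 with an estimated correlation.

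R and NR both received the PD-1 antibody on top of PLX+PTX, and their comparison asks what set these tumours apart. Gzmb averaged 35.1 ± 7.76 normalised counts in R and 13.0 ± 1.77 in NR (SD, n = 3 each; log2 fold change 1.44, SE 0.30, adjusted p = 0.155), with all 3 R libraries above all 3 NR libraries. Gzma averaged 16.4 ± 5.64 against 4.75 ± 2.65 (log2 fold change 1.77, SE 0.48, adjusted p = 0.407). Batf3, a transcription factor of cross-presenting dendritic cells, averaged 22.6 ± 1.28 against 11.3 ± 3.78 (adjusted p = 0.555). Fgf13, Cntfr and the tryptophan-degrading enzyme gene Tdo2 completed the 6 genes of smallest p, with log2 fold changes of 1.35, 1.49 and 1.22 (adjusted p = 0.155, 0.273 and 0.273); none of the 6 passed. All 6 lay near background: the raw Gzmb counts passed the detection limit in 1 of 3 libraries of each group. Csf1r averaged 129 ± 41.8 against 102 ± 30.5, and Mki67 1688 ± 192 against 2020.03 ± 477. Cd274 and Itgae had log2 fold changes of −0.24 (SE 0.46) and 0.50 (SE 0.54).

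Gene lists of lymphocytes and dendritic cells had medians above 0 in R relative to NR, and none passed. The CD8 and cytotoxic effector list had a median log2 fold change of 0.75 (6 of 7 members above 0), and 2 of its genes, Gzmb and Gzma, passed when adjusted over the list alone. The lymph node and lymphoid tissue list had a median of 0.71 (5 of 5 above 0), the dendritic cell list 0.50 (8 of 9, with Batf3 the 1 gene that passed adjusted over the list alone) and the T cell list 0.27 (7 of 8). Their adjusted p by fry was 0.0919 in each case, and 0.373 (CD8 and lymph node), 0.415 (dendritic) and 0.706 (T cell) with an estimated correlation in camera. The dendritic list alone passed the mixed test (adjusted p = 0.0262). Beside these medians, the 148 probes detected in no library had a median log2 ratio of 0.61 (quartiles 0.26 and 0.88), and the scaled negative controls averaged 20.9 ± 2.63 in R and 11.9 ± 2.28 in NR (SD, n = 3 each). The proliferation list had a median of −0.19 (14 of 17 below 0), the macrophage list 0.07 and the type I interferon list 0.31, none of them past fry.

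The test of R against NR gave 0 changed genes of 615 by edgeR's quasi-likelihood test, with 42 at an unadjusted p under 0.05; DESeq2 and limma-voom gave 0 too, as did the fit without the 3 libraries of low signal. Without PLX+PTX+aPD-L1 replicate 1, or without replicate 2, 3 lists passed fry in place of 0 (T cell, CD8, and lymph node), and with its preset correlation camera called 4 (CD8, dendritic and lymph node upward, proliferation downward). The median of all 615 genes was 0.11 with housekeeping scaling.

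**Figure D2:**
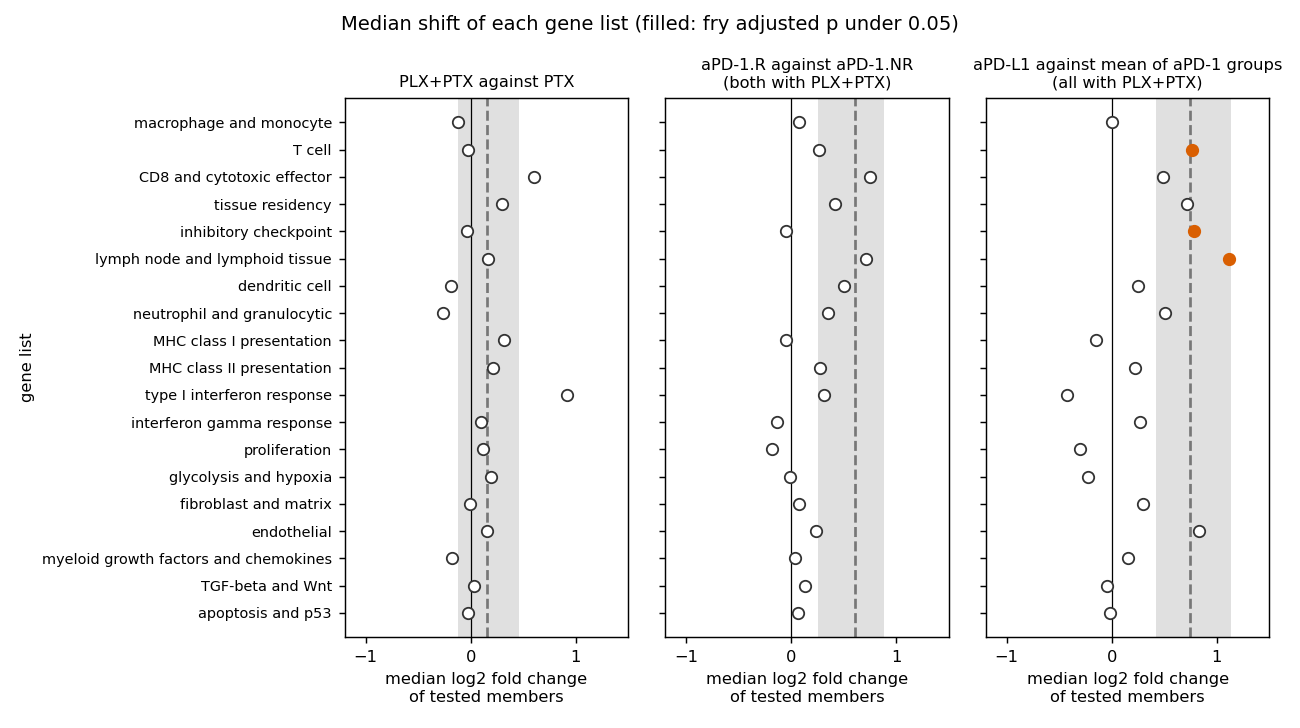
Median log2 fold change of the tested members of each of 19 gene lists in 3 comparisons, with filled circles for lists past fry at an adjusted p under 0.05; the dashed line and grey band are the median and quartiles of the 148 probes detected in no library. In the panel of R against NR the CD8 list (0.75) and the lymph node list (0.71) lie close to the line at 0.61, and in the panel of PLX+PTX+aPD-L1 the T cell (0.76) and checkpoint (0.78) lists lie close to the line at 0.74.

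Tumours of the R group were also set against PLX+PTX without an antibody. The amino acid transporter gene Slc7a5 averaged 612 ± 230 normalised counts in R (n = 3) and 337 ± 60.3 in PLX+PTX (n = 2; SD), with a log2 fold change of 0.86 (SE 0.31). Tnfrsf18, which encodes the costimulatory receptor GITR, averaged 33.9 ± 5.64 against 60.8 ± 12.1, and the RNA sensor gene Tlr8 22.9 ± 1.84 against 43.1 ± 0.568. The chemokine gene Ccl20, Clec4e and Fgf13 had log2 fold changes of 1.32, 0.99 and 0.80 (SE 0.35, 0.37 and 0.32), and none of these 6 genes passed (adjusted p = 0.979). Ccl20 and Clec4e were above the detection limit in no library of either group, and Fgf13 in 1 R library. The scaled negative controls averaged 20.9 ± 2.63 in R and 14.8 ± 2.43 in PLX+PTX. Csf1r, Gzmb, Itgae, Cd274 and Mki67 had log2 fold changes of −0.34, 0.39, 0.05, −0.02 and −0.22. The type I interferon list had a median of −0.64 (15 of 16 members below 0) and the macrophage list one of −0.38 (15 of 17 below 0). Neither passed fry (adjusted p = 0.926 for both), 0 of their genes passed adjusted over the list alone, and camera called both with its preset correlation (adjusted p = 0.00804) and neither with an estimated one (0.934). By edgeR's quasi-likelihood test 0 of 615 genes changed, with 15 at an unadjusted p under 0.05, and DESeq2 and limma-voom gave 0.

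In NR relative to PLX+PTX, the granule protease genes had the smallest p-values. Gzma averaged 4.75 ± 2.65 in NR (n = 3) and 18.2 ± 0.171 in PLX+PTX (n = 2; SD), and Gzmb 13.0 ± 1.77 against 27.0 ± 7.34, with log2 fold changes of −1.88 (SE 0.51) and −1.05 (SE 0.33). Tbxas1, the thromboxane synthase gene, averaged 20.3 ± 2.53 against 37.3 ± 1.0001, while Cd40, the B cell survival factor gene Tnfsf13b and Tdo2 had log2 fold changes of −0.94, −0.91 and −0.92. None of these 6 genes passed (adjusted p = 0.929). Gzma was above the detection limit in 0 of 3 NR libraries and Gzmb in 1, and each in 1 of 2 PLX+PTX libraries. In NR the Gzma mean lay under the scaled negative controls (11.9 ± 2.28) and the Gzmb mean close to them. Csf1r averaged 102 ± 30.5 against 164 ± 43.2 (log2 fold change −0.70, SE 0.42), and Itgae, Cd274 and Mki67 had log2 fold changes of −0.46, 0.22 and 0.04. All 16 type I interferon genes lay below 0 (median −0.69), as did all 5 of MHC class II presentation (median −0.95) and 15 of 17 macrophage genes (median −0.62). The lymph node and CD8 lists had medians of −0.65 and −0.61, with 0 and 2 genes past the threshold adjusted over the list alone, and the proliferation list one of 0.12. No list passed fry (smallest adjusted p = 0.164), while camera called 6 with its preset correlation and 0 with an estimated one (smallest adjusted p = 0.550).

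The median of all 615 genes in this comparison was −0.18, and the scaled negative controls averaged 11.9 ± 2.28 in NR and 14.8 ± 2.43 in PLX+PTX. By edgeR's quasi-likelihood test 0 genes changed, with 23 at an unadjusted p under 0.05, and DESeq2 and limma-voom gave 0. Without the 3 libraries of low signal the T cell, lymph node and endothelial lists passed fry; without either PLX+PTX+aPD-L1 library the lymph node list did.

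Tumours given the PD-L1 antibody stood apart from PLX+PTX in 14 genes, all of them higher. Cxcl15, a neutrophil-attracting chemokine best known from lung epithelium, averaged 2156 ± 1850 normalised counts in PLX+PTX+aPD-L1 and 13.2 ± 0.165 in PLX+PTX (SD, n = 2 each; log2 fold change 7.34, SE 1.41, adjusted p = 0.0124). Hc, which encodes complement component 5, rose from 12.3 ± 1.40 to 232 ± 215, and the histamine-forming enzyme gene Hdc from 13.7 ± 2.12 to 142 ± 28.1 (adjusted p = 0.00369 for both). The signalling ligand gene Wnt11 rose from 10.96 ± 1.96 to 105 ± 13.3 (log2 fold change 3.26, SE 0.49, adjusted p = 0.00369), and the interferon-induced Ifitm1 from 17.3 ± 0.227 to 133 ± 36.4 (adjusted p = 0.00478). Zap70, a kinase of the T cell receptor, rose from 11.04 ± 4.53 to 71.5 ± 9.18 (adjusted p = 0.00369). In PLX+PTX these 6 genes were not above the detection limit in either library, so the folds rest on a level near background there. Csf1r, Gzmb, Itgae, Cd274 and Mki67 had log2 fold changes of −0.47, 0.16, 0.79, 0.89 and −0.58, and none passed (adjusted p = 0.382 to 0.895).

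The T cell and the lymph node lists passed fry upward in PLX+PTX+aPD-L1 relative to PLX+PTX, with medians inside the quartiles of background probes. The 148 probes detected in no library had a median log2 ratio of 0.65 (quartiles 0.34 and 1.11) in this comparison, above the T cell median of 0.47 and below the lymph node median of 1.06. In the T cell list 2 of 8 tested genes rose, Zap70 and the adhesion receptor gene Cd2 (log2 fold change 2.24, SE 0.45, adjusted p = 0.0172), and the same 2 passed adjusted over the list alone. Cd2 was above the detection limit in neither PLX+PTX+aPD-L1 library, and the T cell receptor component Cd3g and the costimulatory receptor Cd28 had log2 fold changes of 1.16 and 0.45 that did not pass. The list passed fry with an adjusted p = 0.00578 (adjusted p = 0.176 with an estimated correlation in camera); after subtraction of the negative controls its median was −0.12, against the upward direction of the test. In the lymph node list, the lymphoid chemokine genes Ccl19 (1.06), Ccl21a (1.81) and Cxcl13 (0.60) did not pass (fry adjusted p = 0.00757; adjusted p = 0.176 with an estimated correlation). The type I interferon list had a median of −1.05 and the checkpoint list one of 0.86, and neither passed the directional test (fry adjusted p = 0.664 and 0.321), with 1 gene in each past the threshold adjusted over the list alone. Both passed the mixed test, which asks for change in either direction (adjusted p = 0.0411 and 0.0153), as did 8 of the 19 lists in all.

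Both PLX+PTX+aPD-L1 libraries were of low signal, and their scaled negative controls averaged 27.2 ± 7.50 against 14.8 ± 2.43 in PLX+PTX. Of 615 genes 14 changed by edgeR's quasi-likelihood test (99 at an unadjusted p under 0.05), 12 of them above the detection limit in both PLX+PTX+aPD-L1 libraries. DESeq2 called 26, limma-voom 14, and limma on the deposited log2 values 0. On the probes above the limit in 10 or more libraries edgeR also called 0. Cxcl15, Hc, Hdc, Wnt11, Ifitm1 and Zap70 were above it in at most 4 of 12 libraries, so that filter left them untested. Without PLX+PTX replicate 1 the count was 3 and neither list passed (adjusted p = 0.0609 for T cell and 0.0842 for lymph node), and without PLX+PTX replicate 2 the count was 0; without PLX+PTX+aPD-L1 replicate 1 the number of lists was 6.

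Setting the PD-L1 antibody against both PD-1 antibody groups gave the highest number of differences in the series: 35 genes were higher in PLX+PTX+aPD-L1 than in the mean of R and NR, and 0 were lower by edgeR's quasi-likelihood test, while the deposited log2 values gave 28 higher and 33 lower. Cxcl15 averaged 2156 ± 1850 normalised counts (SD, n = 2) against 58.2 ± 101 over the 6 R and NR libraries (log2 fold change 5.64, SE 0.81, adjusted p = 0.000993). Sox2 averaged 119.9 ± 6.20 against 14.9 ± 3.57 (log2 fold change 3.03, SE 0.25, adjusted p = 2.9e-05). Hc, Hdc and Ifitm1 had log2 fold changes of 3.93, 3.79 and 3.24 (SE 0.43, 0.39 and 0.36; adjusted p = 0.000103, 9.9e-05 and 0.000103). Ccl21a, a chemokine that guides naive lymphocytes, averaged 207 ± 86.8 against 23.6 ± 11.97 (log2 fold change 3.09, SE 0.69, adjusted p = 0.0178), and lost its call without PLX+PTX+aPD-L1 replicate 2 (adjusted p = 0.162). Csf1r was nearly level (119 ± 11.1 against 115 ± 35.9; log2 fold change 0.05, SE 0.39), and Gzmb, Itgae, Cd274 and Mki67 had log2 fold changes of 0.49, 0.99, 0.78 and −0.49 that did not pass (adjusted p = 0.328 to 0.443).

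The T cell, lymph node and inhibitory checkpoint lists rose in this comparison. Of 8 T cell genes, Zap70 (log2 fold change 2.68, SE 0.32, adjusted p = 0.00017) and Cd2 (2.01, SE 0.35, adjusted p = 0.00389) rose, 3 passed adjusted over the list alone, and Cd28 (0.83) and Cd3g (0.92) did not pass over all genes. The list's median was 0.76 (fry adjusted p = 0.000324; adjusted p = 0.140 with an estimated correlation in camera). In the lymph node list Ccl21a rose, while Ccl19 (1.12) and Cxcl13 (0.90) did not pass over all genes, and these 3 passed adjusted over the list alone (median 1.12, fry adjusted p = 0.000324; adjusted p = 0.109 with an estimated correlation). Of 7 checkpoint genes, the inhibitory receptor gene Btla rose (1.95, SE 0.30, adjusted p = 0.00163), 2 passed adjusted over the list alone, and Lag3 (0.91), Cd200r1 (0.74) and Cd274 (0.78) did not pass over all genes. The checkpoint median was 0.78 (fry adjusted p = 0.0493; adjusted p = 0.977 with an estimated correlation). Its call was lost on leaving out any 1 of 11 libraries (adjusted p = 0.0508 to 0.479) and held without PLX+PTX+aPD-L1 replicate 1. The macrophage list had a median of 0.00463, a mean of −0.00473 and a directional test pointing up (fry adjusted p = 0.955), and the CD8 list a median of 0.49 (fry adjusted p = 0.171). The mixed test called 11 of the 19 lists.

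In this comparison the 148 probes detected in no library had a median log2 ratio of 0.74 (quartiles 0.42 and 1.13), which is the size of the T cell and checkpoint medians. Of the 35 genes by edgeR's quasi-likelihood test (110 at an unadjusted p under 0.05), 26 were above the detection limit in both PLX+PTX+aPD-L1 libraries and 9 were not; DESeq2 called 45, limma-voom 32 and limma on the deposited log2 values 61. Among the probes above the limit in 10 or more libraries edgeR called 4. Cxcl15, Hc, Hdc, Sox2, Ifitm1 and Zap70 were above it in at most 4 of 12 libraries, so that filter left them untested. Without PLX+PTX+aPD-L1 replicate 2 the count was 16, and without replicate 1 it was 53, with 7 lists past fry in place of 3.

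**Figure D3:**
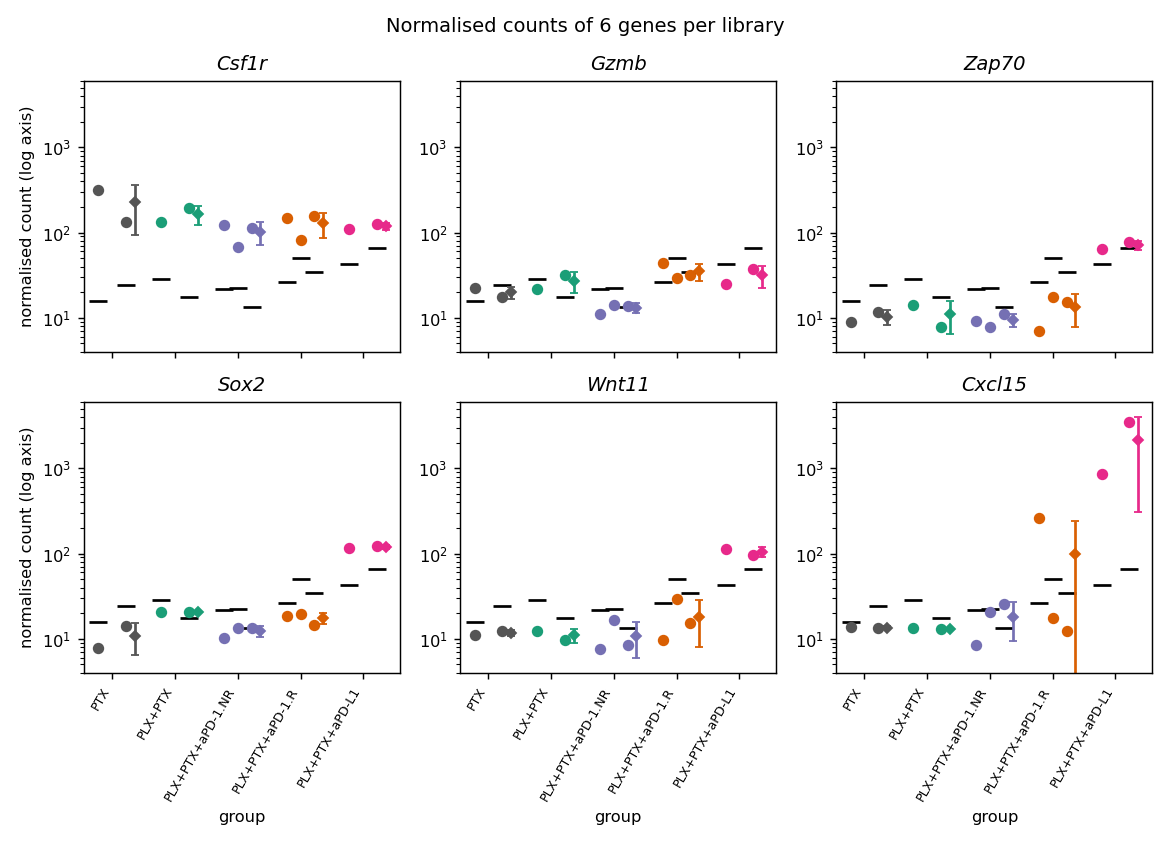
Normalised counts (log axis) of Csf1r, Gzmb, Zap70, Sox2, Wnt11 and Cxcl15 in each library: circles are libraries, black dashes their scaled detection limits, and diamonds with bars the group mean ± SD (the lower bar of Cxcl15 in R runs off the axis because the SD exceeds the mean). Sox2 (mean 119.9), Wnt11 (105) and Zap70 (71.5) lie above the limit in both PLX+PTX+aPD-L1 libraries, while Csf1r (119) is close to its mean of 115 over the R and NR libraries.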

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

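The tests in this part were chosen after the results they bear on had been seen. No group held enough samples for a search for single samples far from the rest, so the one result singled out is a difference between groups given different antibodies on the same PLX+PTX background: 35 genes differed between PLX+PTX+aPD-L1 and the mean of R and NR, tested as that difference itself. The genes include Cxcl15 (log2 fold change 5.64), Hc (3.93), Hdc (3.79) and Sox2 (3.03), each higher in both PLX+PTX+aPD-L1 libraries than the mean of the 6 R and NR libraries.

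A background lifted by scaling low-signal libraries was weighed first. After the negative-control mean had been subtracted, 25 of the 26 genes above the detection limit in both PLX+PTX+aPD-L1 libraries stayed past the threshold. Their median log2 fold change was 2.23 before and 2.10 after, while the probes detected nowhere went from 0.74 to 0. These 26 were picked as called and above the limit, so passing again was likely beforehand and decides little. In 15 of them both raw PLX+PTX+aPD-L1 counts lay above all 6 raw R and NR counts. That argues against background lifted by scaling as the whole cause for those 15. For the others of the 26 the explanation stays open. Of the 9 genes not above the limit in both, 5 stayed past the threshold, so for those 9 it stays open too. For lymph node tissue in the samples, the T cell and B cell lists were examined. Of their members 2 of 27 were above the limit in both libraries (Zap70 at 49 and 27 raw counts, and Cd38). Cd38 was above the limit in all 12 libraries. Low signal hides genes of low count in both libraries, and the lymph node list rose in this comparison. The count of detected members therefore cannot decide whether lymph node tissue was present. A lower share of tumour cells was weighed by the macrophage and monocyte list, whose median was 0.00463 (SD over its members 0.547) beside 2.01 for the 35 genes. Macrophage genes thus did not rise with the 35 genes. All these tumours received the CSF1R inhibitor, and the list does not cover other non-tumour tissue, so the share of tumour cells stays open. Both libraries had low signal, so an effect of the PD-L1 antibody and one of RNA input or handling of these samples could not be separated, and neither was tested.

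The T cell, lymph node and checkpoint lists, which also rose in that comparison, were weighed in the same way. After subtraction the T cell and lymph node lists still passed fry, the larger adjusted p being 0.00167, although their medians went from 0.76 to 0.14 and from 1.12 to 0.55. Fry does not compare a list with other genes and can pass on a few members. Of the T cell list, 1 member was above the detection limit in both PLX+PTX+aPD-L1 libraries. How far background lies behind these 2 calls therefore stays open. The checkpoint list no longer passed (adjusted p = 0.542, median 0.78 before and 0.39 after), which is consistent with background as its source, though the pseudocount of 20 damps low genes as well. An effect of the antibody on these lists stays open and was not tested apart from the low signal.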

How the results depend on the processing

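Subtraction of the negative controls, leaving out the 3 libraries of low signal, and the filter on detection in 10 or more libraries were chosen after the data were seen. In the 4 comparisons without PLX+PTX+aPD-L1, 0 genes passed under each alternative run. For PLX+PTX+aPD-L1 against PLX+PTX (14 genes), DESeq2 gave 26 and a fit of the compared groups alone 24, the filter at 50 counts gave 5, the deposited log2 values and the detection filter 0, and leaving out one library 0 to 18. Against the mean of R and NR (35 genes, none lower), no filter gave 55, the filter at 50 counts 17, counts raised to the limit 148, the deposited log2 values 61 (28 higher and 33 lower), the detection filter 4, and leaving out one library 16 to 53. Subtraction gave 17 and 35 genes, of which 13 and 30 were shared with the 14 and 35. The detection filter could not test genes detected mainly in PLX+PTX+aPD-L1, among them Hc, Hdc, Wnt11, Sox2 and Zap70. Counts raised to the limit were scaled afterwards, so undetected probes end higher in libraries of low signal. The limit was 32.5 and 22.7 counts in the PLX+PTX+aPD-L1 libraries (scale factors 0.753 and 0.346), and 19.1 in NR replicate 3 (1.44). The 148 calls under that setting therefore cannot be told from that lift.

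Of lists past the threshold, PLX+PTX against PTX and R against PLX+PTX had 0, and 3 and 2 by camera with its preset correlation. R against NR had 0, and 4 by that test, 3 with no filter and 0 to 3 on leaving out one library. NR against PLX+PTX had 0, and 6, 1 and 0 to 1 under the same settings, with 3 without the libraries of low signal. PLX+PTX+aPD-L1 against PLX+PTX had 2, and 0 with an estimated correlation, with either stricter filter and with counts raised to the limit, and 0 to 6 on leaving out one library. Against the mean of R and NR there were 3, and 8 with no filter, 9 with counts raised to the limit, 0 with an estimated correlation or either stricter filter, and 2 to 7 on leaving out one library. Both stricter filters left 11 of 19 lists to test, without the T cell, lymph node and checkpoint lists. Counts raised to the limit lift undetected genes in the libraries of low signal, so the 9 lists cannot be told from that lift. For the other changes the cause was not tested.

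Named genes had 1866 values under alternatives: 1784 kept their sign and side of the threshold, 29 lost their call, 9 gained one, 44 changed sign without passing and 0 reversed. Of the 29 losses 28 were in PLX+PTX+aPD-L1 against PLX+PTX, which gave 404 of the values. Most of the 1866 values belong to genes that did not pass in the main fit and so had no call to lose. A gene removed by a filter gave no value and is not among the losses. DESeq2 gave Cxcl15 no adjusted p in either comparison with PLX+PTX+aPD-L1. Against PLX+PTX, Zap70 and Cd2 lost their calls with counts raised to the limit (log2 fold changes 1.57 and 1.16), and after subtraction the T cell list passed upward although its median was −0.12. TMM scaling moved the median of all genes from 0.11 to −0.03 in R against NR, from −0.18 to 0.03 in NR against PLX+PTX and from 0.10 to −0.01 in PLX+PTX+aPD-L1 against the mean of R and NR. A library left out of a pair leaves a lone sample, taken to vary like the other groups. Leaving out the libraries of low signal could not be run for PLX+PTX+aPD-L1, which has no others. No paired analysis was possible because the labels give no replicate numbers. Signal over background limits most the lymphocyte genes, which lie near the detection limit.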

Other observations

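The splits test was set before its result was seen, and the test on background in R against NR after. A few single genes known from vessels were also higher in PLX+PTX+aPD-L1 than in the mean of R and NR, while the endothelial list passed fry's mixed test and not its directional one. Kdr, the main VEGF receptor of endothelium, averaged 264 ± 137 normalised counts (SD, n = 2) against 48.0 ± 20.7 (n = 6), with a log2 fold change of 2.45 and an adjusted p = 0.00186 by edgeR's quasi-likelihood test. The endothelial adhesion gene Icam2 had a log2 fold change of 1.36 (adjusted p = 0.0156), and Pdgfrb, a receptor of pericytes and fibroblasts, one of 1.84 (adjusted p = 0.00709). The endothelial list had a median of 0.83, with 8 of 10 members above 0, 2 that rose and 3 past the threshold adjusted over the list alone, a directional adjusted p = 0.144 (0.977 with an estimated correlation in camera) and a mixed one of 0.00253. Its directional adjusted p passed with no filter (0.0460), with counts raised to the detection limit (0.0250) and without PLX+PTX+aPD-L1 replicate 1 (0.00152), and not under the other alternatives, among them subtraction of the negative controls (0.542). The pass with counts raised to the limit cannot decide this, because that setting lifts undetected probes in libraries of low signal. In the fibroblast and matrix list 1 of 13 genes rose (directional adjusted p = 0.456, mixed 0.00253). These genes were chosen after their values were seen.

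Single genes of other kinds differed as well, and they share no list. The chemokine gene Cxcl12 averaged 429 ± 50.6 in PLX+PTX+aPD-L1 and 98.1 ± 31.0 over the 6 R and NR libraries (log2 fold change 2.14, adjusted p = 0.000646), and was above the detection limit in all 8 of them. The interleukin-6 receptor gene Il6ra averaged 324 ± 4.09 against 89.5 ± 38.2 (adjusted p = 0.0066), S100a9 92.8 ± 28.1 against 18.9 ± 7.83 (adjusted p = 0.0253), and the lysozyme gene Lyz1 4425 ± 3030 against 1320.1 ± 309 (adjusted p = 0.0165). In the list of myeloid growth factors and chemokines 1 of 12 genes rose, Cxcl12; the list had a median of 0.16 and did not pass the directional test (adjusted p = 0.171), but passed the mixed one (adjusted p = 1.8e-07), with 3 genes past the threshold adjusted over the list alone. These genes too were chosen after their values were seen.

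The medians of the CD8, lymph node and dendritic lists in R against NR (0.75, 0.71 and 0.50) lie near the median of probes detected in no library, 0.61. The T cell median of 0.27 lies lower, near the lower quartile of those probes, 0.26. After the negative-control mean had been subtracted, the largest of these 4 medians was 0.0888, which is consistent with background lifted by scaling as a source of the shift, though the pseudocount of 20 also damps low genes. A difference between R and NR tumours in these cells stays open. The 6 libraries can be split in 10 ways, too few for a share under 0.05: the real split gave 0 genes, the highest of the others gave 0, and so all 10 gave as many. At an unadjusted p under 0.05 the real split gave 42 genes and the highest of the others 55.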
